A study of Escherichia coli with 15 samples.

How the data were processed

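RNA levels of Escherichia coli were compared on 15 DNA arrays read in 2 colours, each holding a culture sample against a reference sample. Per the labels, 7 arrays carry wild-type cells grown in Davis medium with glucose, and 8 carry the lexA strain, which the series title describes as deficient in the SOS response. Wild-type cells were sampled at 5, 10, 20, 40 and 60 min after UV and at 20 and 60 min without UV, with 1 array per time. The labels give 40 J for the irradiated wild-type arrays and give no dose for the lexA arrays. The lexA strain was sampled at the same times with and without UV, and 1 further array sets it against wild type before UV. The lexA allele is not given in the sources used here. Groups were taken from the array titles and, for the lexA strain, from the source labels. For the wild-type 5 and 40 min arrays the source label reads untreated while the title and the lot label name UV, and these arrays were analysed as irradiated. The arrays of each strain form 1 table on its own array design, so strain and table differ together.

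The deposited values are signed log ratios of the channels of each array, read here as log2 ratios. The authors' labels name ScanAlyze 2.24 as the scanning software and state neither the log base, the normalization, the background treatment nor the filter behind blank values. Base 2 is an assumption from the range of the values, and every log2 value and fold given here rests on it. The direction, culture sample over the reference taken before UV, is likewise not stated as such: the titles word it so, but the channel order in the labels is opposite in the 2 tables, so signs are given as likely. The tables hold no spot intensities, so signal over background is unknown. A value was present for 87.85% to 92.42% of the 4896 wild-type probes and for 93.81% to 95.84% of the 5764 lexA-table probes. Array medians ran from -0.04 to 0.16 in the wild-type table, with 0.16 on the 5 min array, and from -0.02 to 0.02 in the lexA table. The SD of the log2 ratios was 0.74 to 1.13 in the wild-type table and 0.30 to 0.45 in the lexA table.

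Probes with 1 gene symbol numbered 4111 in the wild-type table and 4624 in the lexA table, for 4095 genes in each, of which 4094 matched the reference gene table of assembly ASM584v2, used for names only. Of the 785 and 1140 probes without a symbol, 252 and 797 had enough values and were tested apart. Each array was centred on its median and the probes of a gene were averaged. More than 1 probe stood for 529 genes in the lexA table, and the correlation between duplicate probes of a gene was low, from 0.01 to 0.28 per array, so averages of such genes are less certain. Names wrong throughout that design would not give the r of 0.88 between the contrasts of the 2 designs over 242 genes called in the lexA strain, while wrong names of single probes were not tested for. Genes with values on at least 4 of 5 irradiated arrays and on both unirradiated arrays were tested, 3739 in wild type, 4022 in the lexA strain and 3674 for the difference between strains.

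Irradiated and unirradiated arrays were compared within each strain, and the difference of both contrasts was tested over the 14 arrays, with lmFit and eBayes of limma 3.58.1 in R 4.3.3 and Benjamini-Hochberg adjustment at a threshold of 0.05. The 5 times served as samples of an irradiated group because each time has 1 array, so the spread includes change over time. Residual degrees of freedom were 5 within a strain and 10 for the difference. The test of the difference pools the residual variance of both tables for each gene, although the ratios of the lexA table spread less. Nothing in the labels says whether the times come from separate cultures, so the p-values measure only the spread between these arrays, whose number limits the precision. The median SE over genes was 0.25 in wild type, 0.10 in the lexA strain and 0.28 for the difference. The 20 gene lists were tested with the statistic of camera on limma's moderated z values at a preset correlation of 0.01, again with a correlation estimated from the residuals, and with fry, all adjusted over the 20 lists. The lists were also compared by an exact two-sided permutation test of array means over the 21 ways to part 7 arrays into 5 and 2, whose smallest possible p is 0.0476 and which was not adjusted over the lists. It was planned for the core LexA list, and the other lists were added. Single arrays were set against the mean of both unirradiated arrays without a test, as was the array of the lexA strain against wild type, whose list medians were placed among 10000 random lists of equal size. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

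The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. Per tested comparison that rule takes the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, within a strain only those with every irradiated array on the same side of both controls. Where fewer than 5 passed in a direction, the genes with the smallest p fill the list to 5, as values that did not pass. Any LexA-list member may be named, and of other lists the 4 members with the smallest p. For the array before UV the 10 highest and 10 lowest genes are taken. Genes named outside this rule are said to be so.

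Alternatives covered the deposited values without centring, other array scalings, stricter and looser filters on missing values, robust and array-weighted fits, time as a covariate, the 20 and 60 min arrays alone with time as a block, irradiated arrays against the reference without the controls, the median of probes, a fold threshold, and each array left out in turn. Added after the data were seen were scaling of the lexA table to the wild-type spread, separate variances per strain, the lexA table turned in sign, genes with 1 probe, and the 20, 40 and 60 min arrays alone. The fits were tested on simulated data with 50 genes shifted per size. Of shifts of 1 on the log2 scale, the wild-type comparison recovered 38% among its 3739 genes, the lexA comparison 94% among 4022, and the difference between strains 52% among 3674. Of shifts of 2, they recovered 88%, 100% and 76%, and of shifts of 0.5, 4%, 70% and 8%. In the same order, unshifted genes made up 4 of 117, 8 of 190 and 11 of 126 calls. The simulated noise was normal and independent between genes, without change over time.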

Results

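The data describe RNA levels in wild-type E. coli and in an SOS-deficient lexA strain over 60 min after UV. Each strain has 5 irradiated arrays, at 5, 10, 20, 40 and 60 min, and 2 unirradiated arrays, at 20 and 60 min. A further array sets the lexA strain against wild type before UV. There is 1 array per time, so an SD over irradiated arrays spans the times. All values are log2 ratios of a culture over its reference taken before UV, with base 2 assumed and the direction likely but not stated.

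The comparison within wild type asks which transcripts differed after UV in cells with a working SOS response. Genes repressed by LexA, the SOS repressor, made up 19 of the 22 rises. The largest was recN (Entrez Gene 947105), which acts in repair of double-strand breaks. Its log2 ratio was 4.74 ± 0.20 (SD, n = 5) after UV against a mean of 0.36 in the 2 controls, a 20.9-fold rise (SE 0.19 on the log2 scale, adjusted p = 7.04e-05). The division inhibitor sulA (947335) rose 10.0-fold, from 0.24 to 3.56 ± 0.30 (adjusted p = 0.00142). The gene of the recombinase recA (947170) rose 10.3-fold, from -0.61 to 2.75 ± 0.51 (adjusted p = 0.00868), and lexA itself (948544) 5.01-fold, from -0.78 to 1.54 ± 0.24 (adjusted p = 0.0040). Also among the 10 largest rises were dinD at 10.9-fold, dinB, the gene of DNA polymerase IV, at 10.7-fold, yebG at 9.18-fold, and recX and dinI, which modulate RecA, at 8.95-fold and 4.65-fold. The remaining one, yihV, rose 4.83-fold, but its irradiated mean was -0.28 ± 0.32 and its control mean -2.55, so the difference lay in low control values. Each of these 10 genes lay above both controls on 5 of 5 irradiated arrays.

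Of the 22 core LexA genes, 15 rose and 7 did not pass over all genes tested, and 20 rose when adjusted over the list alone. Those that rose include the excision repair genes uvrA (1.99), uvrB (2.10) and uvrD (1.39), the Holliday junction gene ruvA (1.87) and polB, the gene of DNA polymerase II (1.73). The subunits of DNA polymerase V had large differences that did not pass, 4.16 for umuC (SE 0.69, adjusted p = 0.0536) and 3.93 for umuD (SE 0.75, adjusted p = 0.10). Their irradiated means varied widely over the times, 4.10 ± 1.11 and 3.72 ± 1.19 (SD, n = 5). The others not passing were ruvB at 1.00, dinG at 0.88, sbmC at 0.82, ssb, the single-strand binding protein gene, at 0.41 and ftsK at -0.29. The core mean was 1.92 ± 0.27 (SD, n = 5) after UV and -0.39 in the controls, a shift of 2.31 (camera adjusted p = 1.66e-31), and the exact permutation test gave p = 0.0476, the smallest it can give. With an estimated correlation the call was lost (adjusted p = 0.109). Of 13 further LexA targets 4 rose, namely cho, an endonuclease of excision repair, at 1.82, rmuC at 2.00, the toxin gene yafO at 1.88 and yebE at 1.31. Adjusted over the list alone 11 rose. Their mean shift was 1.23 (camera adjusted p = 5.15e-12), and the adjusted p = 0.154 with an estimated correlation.

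In all, 24 of 3739 genes passed in wild type, 22 higher and 2 lower, where 504 had an unadjusted p under 0.05. Genes with every irradiated array above both controls numbered 437, and 366 lay below, against 9.52% expected by chance in both directions together. The 2 genes that fell were dosC, a diguanylate cyclase, at -1.84 (SE 0.21, adjusted p = 0.0110), and minE (945740), which helps to place the division septum, at -1.60 (SE 0.24, adjusted p = 0.0316), each below both controls on 5 of 5 irradiated arrays. Over the reference minE stood at -0.10 at 5 min and between -0.88 and -0.70 at the other times. Part of its difference thus lay in controls above the reference. Of the operon of minE, minC (-1.62, adjusted p = 0.0665) and minD (-1.17, adjusted p = 0.173) did not pass, and neither did igaA (-1.75) and yddB (-1.38). Under alternatives minC passed with arrays scaled (-1.74), quantile normalization (-1.83), array weights (-1.73) and without the 5 min array (-1.77), igaA with array weights (-1.71) and against the reference alone (-0.53), and yddB with array weights (-1.45). Outside the LexA lists yoaA (1.18) and ybhK (1.30) also rose, named after their values were seen to complete the 24. Without the 60 min control 4 genes passed, without the 20 min control 13 and without the irradiated 40 min array 13. The genes recN, dinD and sulA passed without each array in turn. The other 9 named genes that passed, dinB, recA, yebG, recX, lexA, yihV, dinI, dosC and minE, did not pass without the 60 min control. Their values were then from 2.21 for yihV to 3.52 for recA and -1.77 for dosC and -1.52 for minE. Of these, 7 (not dinB and lexA) also did not pass without the 20 min control, nor minE without the irradiated 10, 20, 40 or 60 min array (-1.59 to -1.55) and dinI without the 10 or 40 min array (2.18 and 2.22). On the values as deposited, without centring, minE did not pass (-1.60, adjusted p = 0.0750), and with time as a covariate neither minE (-1.65, adjusted p = 0.0716) nor dinI (2.18, adjusted p = 0.0580) did. Without both arrays whose source label reads untreated 11 genes passed, but not recA (3.37), recX (3.08), yihV (2.18), dinI (2.29) and dosC (-1.73), and with the 20 and 60 min arrays alone, blocked by time, 0 passed in limma, where 211 had an unadjusted p under 0.05.

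**Figure D1:**
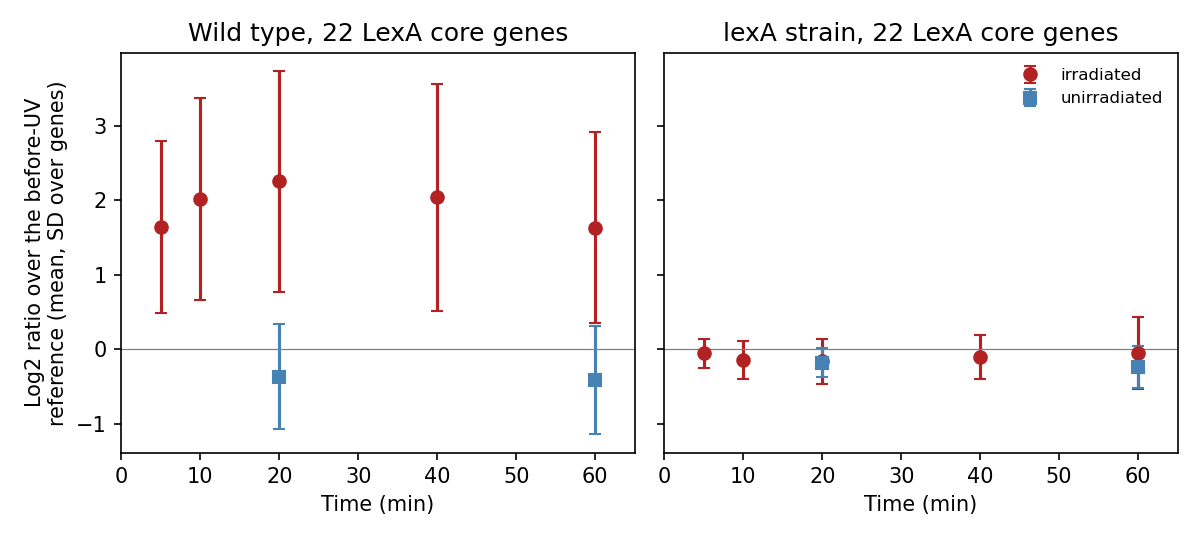
Mean log2 ratio of the 22 core LexA genes on each array against time in min, with bars for the SD over genes, for irradiated (circles) and unirradiated (squares) arrays of wild type (left) and the lexA strain (right). Wild-type irradiated arrays lie between 1.63 and 2.25 and the wild-type controls at -0.37 and -0.42, whereas irradiated arrays of the lexA strain lie between -0.16 and -0.05.

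Outside the LexA genes, lists of translation, replication, purine and pyrimidine synthesis, heat shock and respiration genes were higher after UV in wild type. General stress and amino acid synthesis lists were lower, though amino acid synthesis stood above the controls at 40 and 60 min (0.10 and 0.17). By camera 10 of 20 lists passed, both LexA lists included, 8 higher and 2 lower. With an estimated correlation 0 of them passed by camera, where 3 had an unadjusted p under 0.05, and 4 passed by fry. Genes of translation factors and RNA polymerase shifted by 0.52 (20 genes, adjusted p = 2.26e-08, and adjusted p = 0.292 with an estimated correlation). No member passed over all genes and 3 rose adjusted over the list alone, the release factor genes prfB (0.87) and prfC (0.77) and nusG (0.66). Ribosomal protein genes shifted by 0.36 (54 genes, adjusted p = 1.55e-08, and adjusted p = 0.349 with an estimated correlation), with no single member passing, as was the case for the respiration genes. DNA replication genes shifted by 0.38 (26 genes, adjusted p = 2.3e-05, and adjusted p = 0.154 with an estimated correlation). None of its members passed, and values were 0.80 for the gyrase gene gyrB and 0.73 for the helicase gene rep. Purine and pyrimidine biosynthesis shifted by 0.42 (25 genes, adjusted p = 3.73e-05, and adjusted p = 0.475 with an estimated correlation), and of these pyrE (0.93) rose adjusted over the list alone. Heat shock genes shifted by 0.34 (21 genes, adjusted p = 0.0018, and adjusted p = 0.298 with an estimated correlation), with the small chaperone gene ibpB (1.19) rising adjusted over the list alone. Genes of ATP synthase, NADH dehydrogenase I and the terminal oxidases cyo and cyd shifted by 0.25 (27 genes, adjusted p = 0.0032, and adjusted p = 0.292 with an estimated correlation).

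General stress genes shifted by -0.48 in wild type (22 genes, adjusted p = 1.19e-05, and adjusted p = 0.475 with an estimated correlation). None passed over all genes and 5 fell adjusted over the list alone, among them the catalase gene katE (-0.91), talA (-0.94) and the trehalase gene treA (-1.08). Over the reference the list's mean was 0.69 in the controls and 0.22 after UV, so the shift lay in controls above the reference. Against the reference alone, without the controls, the list's mean was 0.18 and did not pass (camera adjusted p = 0.450). Amino acid biosynthesis shifted by -0.20 (82 genes, adjusted p = 0.00769, and adjusted p = 0.624 with an estimated correlation), with no member passing. The 10 lists that did not pass in wild type had means of 0.33 for the cryptic prophage e14, 0.10 for other DNA repair, -0.02 for deoxyribonucleotide synthesis with a median of 0.12, -0.06 for cell division with a median of 0.10, 0.13 for oxidative stress, -0.14 for the tricarboxylic acid cycle, 0.02 for glycolysis with a median of -0.05 and a test sign below 0, -0.18 for flagella and chemotaxis, -0.12 for anaerobic metabolism and 0.06 for cold shock. Adjusted over the list alone, 3 members of cell division fell, minE, minC and minD, and slmA (1.17) rose. In deoxyribonucleotide synthesis dut (0.75) rose and nrdD (-0.98) fell, recF (0.90) of other DNA repair rose and adhE (-0.93) of anaerobic metabolism fell. By the exact permutation test of array means, unadjusted over the lists, 4 of the lists called by camera had a p above 0.05: amino acid biosynthesis (exact p = 0.476), general stress (exact p = 0.143), purine and pyrimidine biosynthesis (exact p = 0.143) and ribosomal proteins (exact p = 0.0952). The other 6 had the smallest p that test can give (exact p = 0.0476). The call of amino acid biosynthesis was lost without the irradiated 5 min array (-0.12), the 10 min array (-0.13) or the 60 min control (-0.10), that of heat shock without the 60 min control (0.21) and that of the respiration genes without the 20 min control (0.21). Amino acid biosynthesis also did not pass with time as a covariate (-0.05), with the time block (-0.06) or with the 20, 40 and 60 min arrays alone (0.00), nor did purine and pyrimidine biosynthesis with the time block (0.16). Against the reference alone amino acid biosynthesis (-0.16), DNA replication (0.14) and the respiration genes (0.14) did not pass.

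**Figure D2:**
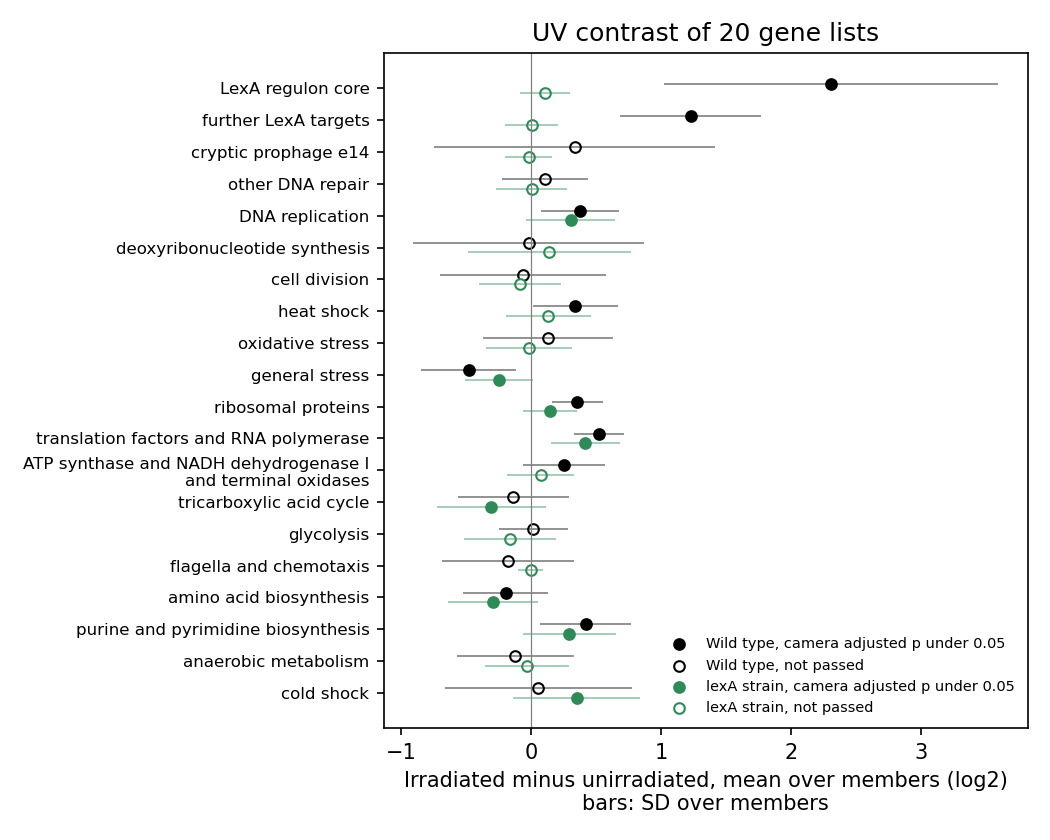
Mean of the irradiated minus unirradiated log2 values over the members of each of the 20 lists, in wild type (black) and the lexA strain (green), with bars for the SD over members and filled points for lists with a camera adjusted p under 0.05 at the preset correlation. The core LexA list stands at 2.31 in wild type and 0.11 in the lexA strain, while general stress lies below 0 in both, at -0.48 and -0.25.

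The same comparison within the lexA strain asks which transcripts differed after UV where the SOS response is deficient. Its signs rest on the likely direction of a table whose channel order in the labels is opposite to that of the wild-type table. The largest rise was of deaD, an RNA helicase gene, from -0.71 in the controls to 0.79 ± 0.28 (SD, n = 5) after UV, 2.83-fold (SE 0.17 on the log2 scale, adjusted p = 0.00438). The gene of the main sigma factor, rpoD, rose 2.15-fold, from 0.27 to 1.38 ± 0.12 (adjusted p = 0.00242), and the primase gene dnaG of the same operon 2.00-fold (adjusted p = 0.00297). Other large rises were plaP, a putrescine importer gene, at 2.74-fold, trhP at 2.41-fold, the fatty acid synthesis gene fabF at 2.26-fold, nlpI at 2.12-fold, yegD at 2.02-fold, the uracil salvage gene upp at 1.91-fold and the RNA helicase gene srmB at 1.86-fold. The 5 largest falls were in galactitol genes: gatZ at -1.90 (SE 0.33, adjusted p = 0.0155), from -0.12 to -2.02 ± 0.57 (SD, n = 5), gatC at -1.74, gatY at -1.68, gatB at -1.58 and gatA at -1.53. The fermentation gene adhE fell by 1.49, the mannose transport gene manX by 1.23, nlpA by 1.23, and aceK, the gene of isocitrate dehydrogenase kinase, by 1.21. A further galactitol gene, gatD, fell by 1.19. Each of these 20 genes lay on one side of both controls on 5 of 5 irradiated arrays.

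In all, 253 of 4022 genes passed in the lexA strain, 138 higher and 115 lower, of which 18 differed at least 2-fold, 7 higher and 11 lower. The count at an unadjusted p under 0.05 was 943. Of the 22 core LexA genes 1 rose over all genes and 1 adjusted over the list alone, in both cases ssb (0.49, SE 0.08, adjusted p = 0.0121). Values that did not pass were 0.34 for recA (adjusted p = 0.0747), 0.58 for uvrB (adjusted p = 0.0836), 0.18 for sulA, -0.07 for recN, -0.02 for umuC and -0.12 for lexA. The core mean was -0.10 ± 0.05 (SD, n = 5) after UV and -0.21 in the controls, a shift of 0.11 that did not pass (camera adjusted p = 0.119, exact permutation p = 0.0952). It passed with quantile normalization (0.16, camera adjusted p = 0.0259) and over genes with 1 probe (0.14, camera adjusted p = 0.0385), and was -0.10 against the reference alone. None of 14 further LexA targets passed over all genes or adjusted over the list alone in limma, and their mean was 0.00. Without the 20 min control 5 genes passed, without the 60 min control 19 and without the irradiated 40 min array 112, and with the 20 and 60 min arrays alone, blocked by time, 28. Of the 20 named genes rpoD and gatD passed without each array in turn. The other 18 did not pass without the 20 min control (deaD then at 1.54 and gatZ at -1.82), and 15 not without the 60 min control. Of the irradiated arrays, the 20 min one ended the calls of gatC (-1.67) and manX (-1.21) when left out, the 40 min one those of gatB (-1.51), gatC (-1.65), manX (-1.14) and upp (0.98), and the 60 min one that of manX (-1.07). With arrays scaled plaP (1.56), trhP (1.34) and upp (1.01) did not pass, with quantile normalization upp (0.54) did not, with a robust fit gatC (-1.74) and manX (-1.23) did not, and manX also not with either other filter on missing values. With the time block fabF (1.36) and upp (0.69) did not pass, and against the reference alone nlpI (0.20) did not.

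In the lexA strain 8 of 20 lists passed by camera, 5 higher and 3 lower. With an estimated correlation 0 of them passed by camera, where 4 had an unadjusted p under 0.05, and 4 passed by fry. Translation factors and RNA polymerase shifted by 0.42 (20 genes, adjusted p = 1.1e-09, and adjusted p = 0.122 with an estimated correlation). Of these, 9 rose over all genes and 12 adjusted over the list alone, among them rpoD, prfB (0.69), tufB (0.59) and infB (0.72). DNA replication shifted by 0.30 (28 genes, adjusted p = 6.47e-06, and adjusted p = 0.122 with an estimated correlation). Over all genes 7 rose and 1 fell, and 11 rose and 1 fell adjusted over the list alone, among the rises dnaG, holD (0.88), gyrB (0.66) and rep (0.53). Cold shock genes shifted by 0.35 (12 genes, adjusted p = 0.000507, and adjusted p = 0.122 with an estimated correlation). Over all genes 3 rose, namely deaD, infB and pnp (0.70), and 7 rose and 1 fell adjusted over the list alone. Purine and pyrimidine biosynthesis shifted by 0.29 (26 genes, adjusted p = 6.12e-05, and adjusted p = 0.551 with an estimated correlation). Of these, 8 rose, among them purB (0.62) and pyrF (0.78), and 9 adjusted over the list alone. Ribosomal protein genes shifted by 0.14 (53 genes, adjusted p = 8.97e-05, and adjusted p = 0.551 with an estimated correlation). Of these, 6 rose, among them rpsQ and rplQ at 0.43 each, and 13 adjusted over the list alone.

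General stress genes shifted by -0.25 in the lexA strain (25 genes, adjusted p = 9.98e-06, and adjusted p = 0.122 with an estimated correlation). Over the reference their mean was 0.23 in the controls and -0.02 after UV. Over all genes 3 fell, katE (-0.85), the pyruvate oxidase gene poxB (-0.60) and treA (-0.50), and 10 adjusted over the list alone. Amino acid biosynthesis shifted by -0.29 (88 genes, adjusted p = 3.52e-06, and adjusted p = 0.551 with an estimated correlation). Here 1 rose and 5 fell, among the falls tyrB (-0.75) and serC (-0.68), and 1 rose and 11 fell adjusted over the list alone. The tricarboxylic acid cycle shifted by -0.31 (17 genes, adjusted p = 0.00451, and adjusted p = 0.551 with an estimated correlation). Here aceK, sucD (-0.45) and sucC (-0.35) fell and lpd (0.39) rose, and 1 rose and 7 fell adjusted over the list alone. Its call was lost without the 20 min control (-0.25). Against the reference alone general stress (-0.02) and cold shock (0.15) did not pass, and with the time block purine and pyrimidine biosynthesis (0.13) did not. The other lists that did not pass had means of -0.02 for the cryptic prophage e14, 0.00 for other DNA repair, 0.14 for deoxyribonucleotide synthesis, -0.08 for cell division, 0.13 for heat shock, -0.01 for oxidative stress, 0.07 for ATP synthase, NADH dehydrogenase I and terminal oxidases, -0.16 for glycolysis, 0.00 for flagella and chemotaxis and -0.03 for anaerobic metabolism. Mean, median and test sign were not all on one side of 0 for e14, other DNA repair, oxidative stress and further LexA targets. Members of these lists that rose over all genes were dut (0.61), slmA (0.52), atpE (0.33), nuoA (0.49), nuoC (0.37) and ackA (0.44). Those that fell were the stress genes katG (-0.52), acnA (-0.45) and dps (-0.62), the uracil glycosylase gene ung (-0.50), the glycolysis genes ptsI (-0.40) and pfkB (-0.44), and adhE. By the exact permutation test, unadjusted over the lists, 4 of the 8 lists called by camera had a p above 0.05: amino acid biosynthesis (exact p = 0.143), and purine and pyrimidine biosynthesis, ribosomal proteins and the tricarboxylic acid cycle (exact p = 0.0952 each). The other 4 had exact p = 0.0476, as had glycolysis, which camera did not call.

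The difference between the strains was tested directly as the wild-type contrast minus the lexA contrast, which removes constant effects of table, dye and reference but not a difference in scale between the tables. It was largest for recN, at 4.46 (SE 0.21, adjusted p = 6.73e-08), followed by umuC at 4.18 (SE 0.75, adjusted p = 0.0160), dinD at 3.38, dinB at 3.27, sulA at 3.14, recX and recA at 3.02 each, yebG at 2.95, frlB at 2.56 and lexA at 2.44. Of the 22 core LexA genes 16 were higher in wild type over all genes and 19 adjusted over the list alone. The mean difference was 2.20 (camera adjusted p = 7.15e-48, and adjusted p = 0.00149 with an estimated correlation). Not passing over all genes were umuD (3.84, adjusted p = 0.0502), polB (1.72), dinG (0.96), sbmC (0.74), ssb (-0.08) and ftsK (-0.11). Of 13 further LexA targets 5 passed, rmuC (2.27), cho (2.04), yafO (1.82), symE (1.44) and yebE (1.23), and 10 adjusted over the list alone, with a mean of 1.20 (camera adjusted p = 4.13e-17, and adjusted p = 0.0159 with an estimated correlation).

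In all, 30 of 3674 genes differed between the strains, 27 higher and 3 lower, where 278 had an unadjusted p under 0.05. The 3 lower ones were igaA at -1.70 (SE 0.28, adjusted p = 0.0126), minE at -1.53 (SE 0.26, adjusted p = 0.0126) and dosC at -1.51 (SE 0.24, adjusted p = 0.00709), while yicL (-1.03) and gabD (-0.84) did not pass. Within wild type alone igaA (-1.75, limma adjusted p = 0.0637) and umuC (4.16, limma adjusted p = 0.0536) did not pass. Nor did ruvB (1.00) and symE (1.23), each at a limma adjusted p of 0.114, or frlB. The calls of these genes here thus draw on the pooled variance and its degrees of freedom. Under alternatives yicL passed with arrays scaled (-1.12), quantile normalization (-1.21), either other filter on missing values (-1.03), array weights (-1.12), and without the wild-type 20 min control (-1.17), 5 min array (-1.08) or 60 min irradiated array (-1.12). The gene gabD passed without the wild-type 60 min irradiated array (-0.88), against the reference alone (-1.40) and with the lexA table turned (-0.73). Of the named genes higher in wild type frlB lies outside the LexA lists and differed by 2.56 (SE 0.44, adjusted p = 0.0160), with a wild-type irradiated mean of -0.08 and a control mean of -2.59. The third list to pass was of ribosomal protein genes at 0.21 (53 genes, camera adjusted p = 0.00145, and adjusted p = 0.707 with an estimated correlation). No member passed, and the mean was -0.14 once the lexA table was scaled to the wild-type spread, and its call was lost without the wild-type 20 min control (0.19) or the wild-type 5 min array (0.16), without the wild-type 5 and 40 min arrays (0.10) and with the time block (0.11). Means of the other 17 lists did not pass and ran from -0.32 for cold shock to 0.31 for the cryptic prophage e14, with general stress at -0.23 (camera adjusted p = 0.0509) and deoxyribonucleotide synthesis at -0.20 against a median of 0.06. The count was 15 without either control of the lexA strain and 73 without the wild-type 20 min control. Of the 13 named genes that passed, 8 passed without each array in turn. Without the 20 min control of the lexA strain, umuC (4.12), igaA (-1.58), minE (-1.54), dosC (-1.46) and frlB (2.62) did not pass, nor did all of these but dosC without its 60 min control, or all but frlB without the wild-type 60 min control. Nor did umuC with arrays scaled (4.19) or frlB with quantile normalization (3.71). With the lexA table scaled, 39 genes passed, 20 higher and 19 lower, but not dinD (3.20), recA (2.19), lexA (2.73), igaA (-1.59), minE (-1.36) and dosC (-0.72). With the 20 and 60 min arrays alone, blocked by time, 5 genes passed. Not among them were sulA (3.19), recX (2.79), recA (3.04), yebG (3.005), frlB (2.585), lexA (2.58), igaA (-2.45), minE (-1.60) and dosC (-1.34). With the lexA table turned in sign 383 passed, 243 higher and 140 lower, all 13 named ones among them.

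**Figure D3:**
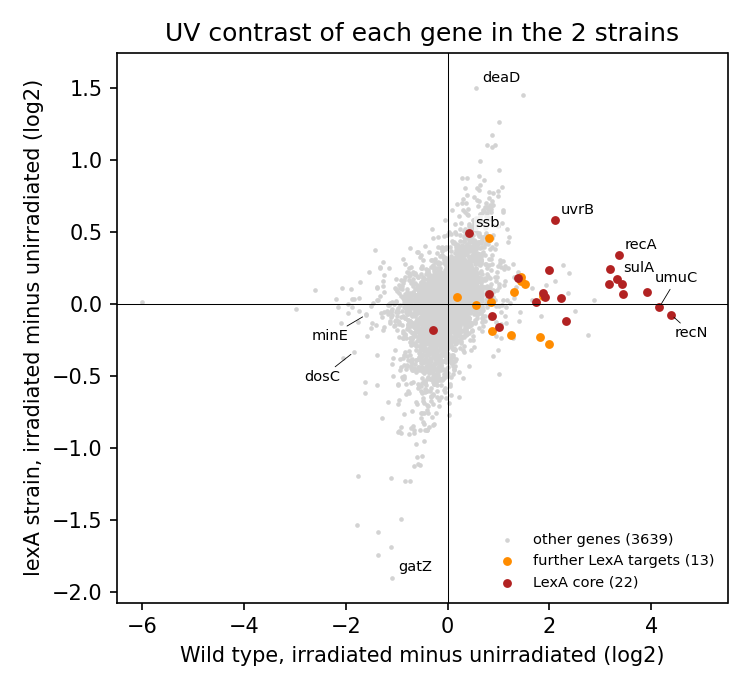
Irradiated minus unirradiated log2 value of 3674 genes in wild type (horizontal) and in the lexA strain (vertical, on a narrower scale), 1 point per gene, with the 22 core LexA genes in red and 13 further LexA targets in orange. Core genes such as recN (4.39 and -0.07) lie far to the right near the horizontal axis, and the other genes follow a rising cloud (rho 0.47 across genes). With the lexA table turned in sign the cloud would fall.

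Genes that changed in the lexA strain were then read in wild type. No gene passed in the same direction in both strains by limma, with 0.8 genes expected for rises if the calls were independent. Small shared changes could seldom pass in both, since wild type recovered 4% of simulated shifts of 0.5 and the lexA strain 70%. Of the 3674 genes, 66.4% had the same sign. All shares here rest on the likely direction of the lexA table, and with that table turned 33.6% had the same sign. At an unadjusted p under 0.05 in both, 145 genes were higher in both, 77 lower in both and 9 opposite. Of 132 genes that rose in the lexA strain and lie outside the LexA lists, 125 had a positive value in wild type, with a mean of 0.54 ± 0.32 (SD over genes), and of 109 that fell 102 had a negative value, with a mean of -0.47 ± 0.38. With the lexA table turned, 7 of 132 and 7 of 109 would share the sign. None of them passed by itself in wild type in limma, where 102 of these 241 had the same direction and 2 the other at an unadjusted p under 0.05. Across 3639 genes outside the LexA lists the contrasts of the strains correlated with r = 0.44 and rho = 0.47, where rho is -0.47 with the lexA table turned. Genes are not independent replicates. Examples of shared sign are adhE (-0.93 in wild type and -1.49 in the lexA strain), katE (-0.91 and -0.85) and prfB (0.87 and 0.69).

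The time course has 1 array per time and no test. Against the mean of both controls, the core LexA genes in wild type stood at 2.03 at 5 min, 2.41 at 10 min, 2.65 at 20 min, 2.43 at 40 min and 2.02 at 60 min. At 5 min umuC was at its lowest, with a log2 ratio of 2.24. Genes at least 2-fold from the controls numbered 493, 324, 378, 289 and 245 in wild type from 5 to 60 min, where the 2 controls differed from each other by as much for 177 genes. In the lexA strain they numbered 72, 35, 24, 32 and 82, against 11 between its controls. With a fold of 3 in place of 2 these counts were 190, 112, 152, 79 and 59 in wild type and 12, 4, 6, 9 and 18 in the lexA strain.

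Some genes were high at late times, and were picked after their values were seen. The ribonucleotide reductase gene nrdA had log2 ratios in wild type of 0.93, 1.11, 1.90, 2.98 and 2.61 from 5 to 60 min, against 1.21 and 0.86 in the controls, and in the lexA strain of 0.07, 0.71, 2.27, 3.53 and 4.36, against 0.79 and 0.45. Its partner nrdB reached 2.49 at 40 min in wild type and 2.84 at 60 min in the lexA strain. The integrase gene intE of the prophage e14 went from -0.08 at 5 min to 4.31 at 60 min in wild type, with controls of 0.69 and 0.42, and stayed at or below 0.20 in the lexA strain, and the excisionase gene xisE went from -0.57 to 2.56 in wild type. The e14 list stood at -0.43, -0.09, 0.25, 0.72 and 1.18 against the controls in wild type, with 7 of 12 members at least 2-fold higher and 1 lower at 60 min, and between -0.04 and 0.01 in the lexA strain. Its members ymfR and pinE rest on single extreme control values of 4.90 and -3.84.

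**Figure D4:**
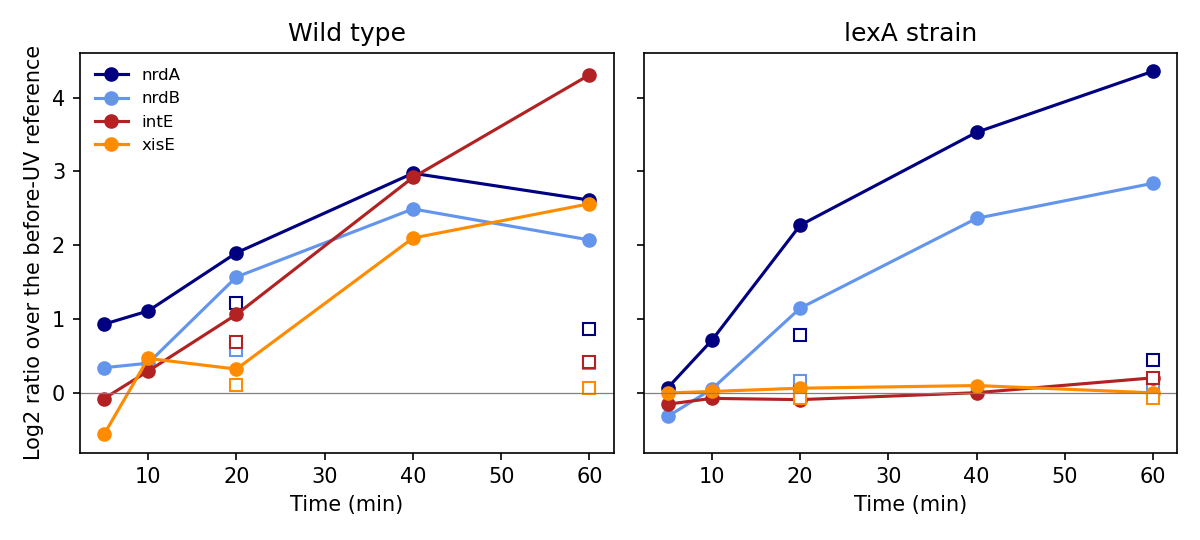
Log2 ratio over the reference before UV against time in min for nrdA, nrdB, intE and xisE in wild type (left) and the lexA strain (right), with lines and circles for irradiated arrays and open squares for unirradiated ones, 1 array per point. At 60 min nrdA stands at 2.61 in wild type and 4.36 in the lexA strain, and intE at 4.31 and 0.20.

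The last array compares the lexA strain with wild type before UV, with no replicate and no test. Duplicate probes of a gene had a correlation of 0.01 over 459 pairs on it, the lowest of the lexA table, and its signs rest on the likely direction of that table. Of 3916 genes 2 were at least 2-fold higher in the lexA strain, katE at 1.45 and ycaC at 1.25, and 1 lower, the riboflavin synthase gene ribC at -1.39. Next came the iron-sulfur cluster genes iscR (0.99) and iscS (0.82), msyB (0.97), yraK (0.93), yeaG (0.89), fbaB (0.83), pdeB (0.81) and amyA (0.81) on the higher side. On the lower side were yiiE (-0.88), recN (-0.55), ygcG (-0.49), znuC (-0.44), yibA (-0.44), cydB (-0.43), panD (-0.42), upp (-0.42) and fruK (-0.40). The core LexA genes had a median of -0.02, at percentile 23.0 of random lists, with uvrA at 0.56, dinG at 0.40 and recA at -0.03. General stress genes had a median of 0.19 (percentile 100 of 10000 random lists), heat shock genes 0.15 (percentile 99.99) and amino acid biosynthesis 0.06 (percentile 99.97). Ribosomal protein genes had a median of -0.07 (percentile 0.07), purine and pyrimidine biosynthesis -0.08 (percentile 0.42) and further LexA targets -0.10 (percentile 1.16). The random lists were not matched on expression level and ignore correlation among the members of a list. The percentiles may therefore overstate how unusual a list is. The median absolute deviation over genes was 0.09.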

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

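The tests that weigh explanations in this part, including the splits of the arrays, were chosen after the results they bear on had been seen, while the test of the difference between the strains was planned. The UV response differed between the strains by the limma test of the difference for recN (4.46), umuC (4.18), dinD (3.38), dinB (3.27), sulA (3.14), recX (3.02), recA (3.02), yebG (2.95), frlB (2.56) and lexA (2.44), all higher in wild type, and for igaA (-1.70), minE (-1.53) and dosC (-1.51), all lower in wild type. By camera it differed for the core LexA genes (2.20), further LexA targets (1.20) and ribosomal protein genes (0.21). With an estimated correlation the 2 LexA lists kept their calls (adjusted p = 0.00149 and 0.0159) and the ribosomal list lost its call (adjusted p = 0.707). The ribosomal difference lies at -0.14 with the lexA table scaled to the wild-type spread.

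Of the 22 core LexA genes 15 rose after UV in wild type and 1 in the lexA strain. Their mean shift of 2.31 in wild type passed by camera but not with an estimated correlation (adjusted p = 0.109). That of 0.11 in the lexA strain did not pass, though it did with quantile normalization (0.16) and over genes with 1 probe (0.14). Narrower ratios in the lexA table do not account for the difference between the strains, because the difference of core shifts was 1.94 after that table was scaled to the wild-type spread, against 2.20 before. A lexA table running in the opposite direction would not account for it either. The core shift in the lexA strain would then be -0.11 (SE over arrays 0.04), far from the 2.31 of wild type. That follows from the small shift of 0.11 by construction and is no separate test. Which direction that table has is left open by this. For the gene counts behind both contrasts, only the real one of the 21 splits of the wild-type arrays gave as many genes as the 24 observed. The highest other gave 7, with the irradiated 20 min and unirradiated 60 min arrays taken as controls. In the lexA strain 1 of 21 gave as many as 253, the real one, and the highest other gave 3. These counts argue against chance but cannot exclude it, since 21 splits give no p below 0.0476. Nor do the labels say whether the arrays come from separate cultures. What remains is a hypothesis, that the rise may depend on a LexA repressor that can be inactivated. It cannot be told apart from other differences between the tables, such as array design or the UV dose not given for the lexA strain. A design or dose that hid UV changes in general is argued against by genes outside the LexA lists called in the lexA strain. Their means there were 0.58 for 132 rises and -0.65 for 109 falls, against 0.54 and -0.47 in wild type. These genes were chosen by their lexA values, and the signs rest on the likely direction. A difference between the tables that is limited to the LexA genes stays open.

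Of 132 genes outside the LexA lists that rose after UV in the lexA strain 125 had a positive value in wild type, and of 109 that fell 102 had a negative one. None of them passed in wild type by limma, where 102 had an unadjusted p under 0.05 in the same direction and 2 in the other. Their mean in wild type, in the direction of the lexA call, was 0.51. In simulation the wild-type comparison recovered 4% of shifts of 0.5, so changes of that size could seldom pass. These shares rest on the direction of the lexA table, which is likely but not stated. With that table turned, 7 of 132 and 7 of 109 share the sign and the mean is -0.51. The unirradiated arrays alone do not settle the direction. Their change from 20 to 60 min had a rho of 0.017 between the strains (error over genes 0.017), and it rests on single arrays. A turned table would require opposite UV changes in the 2 strains for most of the 242 genes called in the lexA strain. As deposited, their contrasts had an r of 0.88 and the same sign in 94.2%. Of the 21 splits of the wild-type arrays only the real one gave as large a mean in the likely direction, and the highest other gave 0.32. That argues against chance but cannot exclude it, since 21 splits give no p below 0.0476. Controls taken at other times than the irradiated arrays are argued against by a mean of 0.43 at 20 and 60 min alone, against controls of the same times. Per wild-type array the mean was 0.56 at 5 min, 0.57 at 10 min, 0.58 at 20 min, 0.55 at 40 min and 0.28 at 60 min. If the tables run the same way, a response to UV that does not need the SOS response is a candidate explanation, but handling of irradiated cultures that the controls did not share was not tested and could give the same pattern.

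The wild-type 5 and 40 min arrays carry a source label that reads untreated. A wrong group is argued against by their core LexA means of 1.64 and 2.04, of which the lower lies 2.00 above the higher of the controls. No biological explanation was tested. Without both arrays 11 genes passed in wild type in place of 24.

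On the wild-type 5 min array minE stood at -0.10 while the other irradiated arrays lay between -0.88 and -0.70, and the cold shock list stood at 0.18 while the others lay between -0.39 and -0.28. These are 2 of 75 sets of arrays examined, where chance gives 3.8. Among probes without a gene symbol 1 of 252 tested in the wild-type table rose, by 1.60, and by limma 0 of 797 in the lexA table changed, where 97 had an unadjusted p under 0.05.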

How the results depend on the processing

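The alternatives with genes of 1 probe, the 20, 40 and 60 min arrays alone, separate variances, and scaling or turning the sign of the lexA table were chosen after the data were seen. The core shift in wild type (2.31) and the difference of core shifts (2.20) kept their direction under every alternative, from 1.92 to 2.38 and from 1.94 to 2.41, and passed under each except that the wild-type shift did not with an estimated correlation (2.31, adjusted p = 0.109). The core shift in the lexA strain passed with quantile normalization (0.16) and for genes with 1 probe (0.14), and was -0.10 against the reference alone. The 24 genes of wild type became 86 with array weights, 11 without the 5 and 40 min arrays, 1824 against the reference alone and 0 in limma with the 20 and 60 min arrays blocked by time, where 211 had an unadjusted p under 0.05 and the arrays number 4. Without 1 array the count ran from 4 to 28. The 253 genes of the lexA strain became 489 with quantile normalization, 434 with time as a covariate, 28 with the time block, 1176 against the reference alone, 454 with the 20, 40 and 60 min arrays and 18 with a fold of at least 2, and ran from 5 to 338 without 1 array. The 30 genes of the difference became 383 with the lexA table turned in sign, 5 with the time block and 1654 against the reference alone, and ran from 15 to 73 without 1 array. Of the lists called by camera, 10 in wild type and 8 in the lexA strain, 0 and 0 passed with an estimated correlation, where 3 and 4 had an unadjusted p under 0.05, and 4 and 4 by fry. Against the reference alone the signs of general stress in wild type (0.18), yihV (-0.28), frlB (-0.18) and yicL (0.30) reversed; that setting leaves out the controls. Ribosomal protein genes reversed in the difference with the lexA table scaled (-0.14). Genes at least 3-fold from the controls, in place of 2-fold, numbered 190, 112, 152, 79 and 59 from 5 to 60 min in wild type and 12, 4, 6, 9 and 18 in the lexA strain. At least 2-fold from the reference alone were 848, 697, 784 and 541 genes from 5 to 40 min in wild type, and 39 at 20 min and 65 at 40 min in the lexA strain. The 3 genes at least 2-fold apart before UV were 3 under both alternatives. For named genes and called lists of wild type, apart from arrays left out, 295 values kept their direction and side of the threshold, 31 no longer passed and 7 newly passed; in the lexA strain 378 kept and 14 no longer passed; for the difference 239 kept, 19 no longer passed and 7 newly passed. Except where fewer arrays, omitted controls or a stricter fold make the change by construction, the cause was not tested. The files hold no intensities, so what signal over background limits is unknown.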

Other observations

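The test of a time course common to both strains and the tests of time in culture were stated before their values were computed but after values per time had been seen, and the margin for the time in culture test was set after its values were seen.

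Several genes named for the lexA strain had another course in wild type, read from 1 array per time and without a test. For rpoD the log2 ratios from 5 to 60 min were 1.07, 0.95, 0.69, 0.44 and -0.16 in wild type, with controls of -0.24 and -0.12, and 1.45, 1.43, 1.24, 1.26 and 1.52 in the lexA strain, with controls of 0.31 and 0.24. The putrescine importer gene plaP went from 2.46 at 5 min to 0.20 at 60 min in wild type, with controls of 0.29 and 0.26, and from 2.30 to 1.26 in the lexA strain, with controls of 0.19 in both. The galactitol gene gatZ was lowest at 20 min in wild type (-1.77) and stood at -0.19 at 60 min, with controls of 0.33 and 0.10, whereas in the lexA strain it was -1.26 at 5 min and -2.81 at 60 min, with controls of -0.04 and -0.20.

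Lists also moved over the times. Amino acid biosynthesis stood at -0.51, -0.46, -0.28, 0.10 and 0.17 against the controls in wild type from 5 to 60 min, and at -0.65, -0.20, -0.09, -0.12 and -0.38 in the lexA strain. General stress genes in wild type stood at -0.39, -0.46, 0.03, -0.77 and -0.79, with the 20 min array apart from the others, and in the lexA strain between -0.29 and -0.18. Translation factors and RNA polymerase stood at 0.76 at 5 min and 0.22 at 60 min in wild type, and between 0.34 and 0.46 in the lexA strain.

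These courses led to the hypothesis that part of the change from early (5 and 10 min) to late (40 and 60 min) times is common to both strains. Across 3288 genes outside the LexA lists the change correlated between the strains with rho 0.37 (r 0.41), the highest of 30 arrangements of the wild-type times, of which the next gave 0.35, so the lead over that one is small. The sign of this rho rests on the likely direction of the lexA table, and a turned table would make it negative. Such a course may exist if the tables run the same way, though each end rests on 2 arrays per strain and genes are not independent replicates. In wild type the change from 20 to 60 min after UV and the same change without UV had a rho of -0.031, under the bound of 0.1 set beforehand. Time in culture is still not settled there. Each change rests on single arrays, whose noise can bring rho near 0, and no controls cover 5 and 10 min. In the lexA strain the same rho was 0.090, which did not clear the bound by a margin of 2 errors over genes (0.017 each). Time in culture stays open there as well, with the same limits.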
